A study of Mus musculus with 2 samples.

How the data were processed

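Trimethylation of lysine 4 on histone H3 (H3K4me3), a histone mark found mainly at active and poised promoters, was mapped by chromatin immunoprecipitation and sequencing in mouse embryonic limb. Per the labels, the tissue came from B6NCrl embryos of both sexes at embryonic day 15.5. The 2 biological replicates were separate pools, with limb from 78 embryos in replicate 1 and from 62 embryos in replicate 2. They form 1 group, and no second tissue, stage or treatment was present, so no test between conditions was possible.

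The deposited data used here were 4 peak lists on mm10. Per the labels and the files' listings, peaks had been called on replicate 1 alone, on replicate 2 alone and on the alignments of both replicates together (the pooled list). The replicated list was derived from the pooled list and both replicate lists. The aligner, the peak caller, their versions and the rule for keeping a replicated peak are not given in the sources used here. Alignments and signal tracks were not analysed here. Each peak carries an enrichment score that the authors' peak caller assigned on its own scale, and it is reported to describe, rank or filter peaks within a list. The deposited lists also give the -log10 of each peak's q value. Read depth per replicate is unknown because the lists hold peaks and no read counts. All intervals on shares are 95% Wilson intervals, and they cover counting error over peaks or genes only. Peaks and genes are not independent replicates, so each p-value below compares gene lists within these libraries and says nothing about variation between limbs.

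Promoters were taken from GENCODE release M21 on GRCm38 (mm10). All 21 chromosomes of the peak lists matched the reference by name, and 0 chromosomes had a peak past their end. A gene was called marked where a replicated peak overlapped the region within 1 kb of any of its annotated transcript starts by at least 1 bp. Peaks were classed as promoter, gene body or intergenic in that order. A domain was a set of replicated peaks merged within 1 kb, and the width at a gene was that of the widest domain at its promoter. The CpG ratio (observed over expected CpG) was computed for a gene within 0.5 kb of its 5' end only. For a peak it was computed over the whole peak. A ratio of 0.6 divided high from low.

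Before the data were examined, 21 gene lists and 8 gene families defined by name pattern were fixed, together with the tests and the naming rule. The lists covered limb patterning transcription factors, limb signalling, chondrocyte, osteoblast, joint and tendon, skeletal muscle, epidermis and endothelium genes. They also covered erythroid, macrophage and leukocyte, Schwann cell and neural crest, hepatocyte, forebrain and neuronal, heart, gut and lung endoderm, and germline and pluripotency genes. The remaining lists held transcription factors of other organs, terminal (differentiation) genes of other organs, imprinted, sex-linked and housekeeping genes. The families were Hox cluster genes, developmental transcription factor families, ribosomal protein, olfactory receptor, vomeronasal receptor, zinc finger protein, keratin-associated protein and replication-dependent histone genes. Every listed gene was found in the annotation. The first 8 lists were grouped as limb lists, and the hepatocyte, neuronal, heart, endoderm and germline lists as other-organ lists. The named genes were those of a fixed panel, the 10 protein-coding genes with the widest domains, the 3 members with the widest domain in each list, up to 3 unmarked members in alphabetical order, and the 5 strongest peaks away from promoters. Where genes shared a domain among the 10 widest, it was counted once, under the gene whose start lay nearest its centre. Any other named gene was chosen after its values were seen.

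The marked share of each list was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 29 lists and families. Where a cell was empty, 0.5 was added to each cell for the odds ratio. The median width of each list with at least 5 marked members was compared with 100000 random lists of the same size from marked protein-coding genes, in a two-sided permutation test adjusted over 23 lists. The smallest p this test can give is 2e-05. Replicate overlap was set against 100 circular shifts of the other list within each chromosome. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

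The functions were tested on simulated data. In 6 of 6 comparisons the overlap counts equalled those of bedtools 2.31.1, and 200 of 200 simulated promoter peaks were recovered. Each simulated peak was placed over a gene's 5' end, so this checks the code and not the rate of false calls. In lists of 20 genes drawn from 14744 marked genes, the width test called 6% of 50 lists widened 1.25-fold, 74% of those widened 1.5-fold and 100% of those widened 2-fold. Among the 150 unchanged lists of each run it called at most 0.667%. For marked shares, with lists of 20 genes from 21911, it called 16% of 50 lists with a true share of 90% and 72% of those with a true share of 30%. A list of this size that failed the share test can therefore differ moderately without being called.

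The alternatives were windows of 0.5 and 2.5 kb, the pooled list, each replicate alone, peaks at or above the list's median enrichment, the gene's 5' end only, merging within 0 bp and 3 kb, a reciprocal overlap of 50%, a background without receptor genes, and a split by CpG ratio with Mantel-Haenszel odds ratios. A threshold of 2 on -log10 q, counting each domain once, leaving out genes that share their window with another coding gene's start, and the CpG ratio as a covariate were added after the data were seen.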

Results

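The data are H3K4me3 peak lists from mouse limb at embryonic day 15.5, with 2 biological replicates of 1 group. Replicate 1 held 28983 peaks covering 36.2 Mb and replicate 2 held 29262 peaks covering 37.9 Mb. Calling on both replicates together gave 30573 peaks, of which the authors' replicated list retained 24086. The replicated peaks covered 39.0 Mb, had a median width of 1443.5 bp and ranged from 190 to 13872 bp. Of these, 725 lay on chromosome X and 7 on chromosome Y. The number of reads behind each list is unknown, so a promoter without a peak is described only as unmarked in these lists. The labels state no question beyond the tissue and the mark; the design allows a comparison of the replicates and of gene groups within the limb.

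The replicates shared their stronger peaks almost completely and parted at the weakest. A peak of replicate 2 overlapped 25454 of the 28983 replicate 1 peaks (87.8%, 95% Wilson interval 87.4 to 88.2%). In the other direction, 24526 of 29262 peaks were overlapped (83.8%, 83.4 to 84.2%). Circular shifts gave at most 3.16%. In the lowest enrichment quartile the shares were 55.8% for replicate 1 and 43.7% for replicate 2, and in the second quartile 95.5% and 91.6%. The overlapped share was 100% in both upper quartiles of either list. In base pairs, 92.9% of the length in replicate 1 and 88.8% of that in replicate 2 was shared. The replicated list retained 90.1% of replicate 1 peaks, 87.3% of replicate 2 peaks and 78.8% of pooled peaks, but only 21.4% of the lowest enrichment quartile of the pooled list. Not every replicated peak overlapped a peak of both replicates. Of the 24086, 23219 did so by at least 1 bp, 299 overlapped replicate 1 only, 560 replicate 2 only and 8 neither. A marked gene therefore need not carry a peak in each replicate. With a reciprocal overlap of 50%, the shared parts fell to 75.9% and 75.2%.

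**Figure D1:**
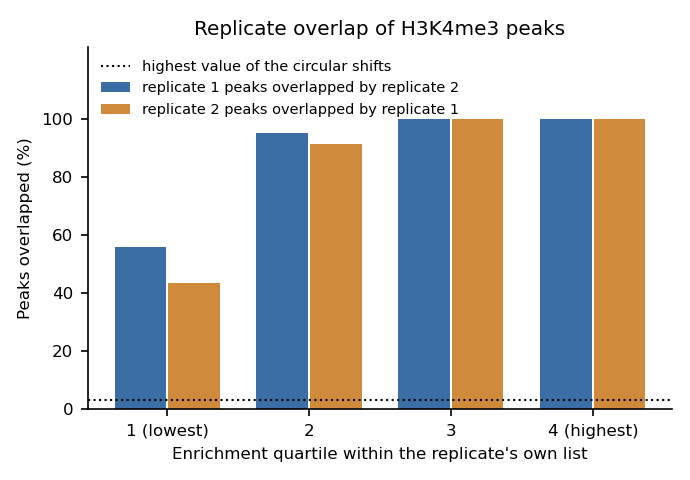
Percent of each replicate's H3K4me3 peaks overlapped by at least 1 bp by the other replicate's peaks (vertical axis), by enrichment quartile within its own list (horizontal axis). Bars are shares over peaks, and the dotted line is the highest of the circular shifts, 3.16%; the shares rise from 55.8% and 43.7% in the lowest quartile to 100% in the upper quartiles.

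Most H3K4me3 in the limb lay at promoters. Of the replicated peaks, 16853 (70.0%, 69.4 to 70.5%) overlapped a promoter, 3791 (15.7%) lay in gene bodies and 3442 (14.3%) were intergenic. Promoter peaks were wider and more enriched, with medians of 1890 bp and 46.2, against 583 bp and 4.45 in gene bodies and 627 bp and 5.75 between genes. A CpG ratio above 0.6 over the whole peak was found in 45.9% of promoter peaks, 18.6% of gene body peaks and 19.8% of intergenic peaks. Among the peaks at or above the list's median enrichment, 96.1% were at promoters, and with only the gene's 5' end as start the share was 59.9%.

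Of 21911 protein-coding genes, 14744 (67.3%) carried the mark at a promoter. The replicates alone marked 67.6% ± 0.0323 (SD, n = 2). Both replicates marked 14692 genes, replicate 1 alone 116 and replicate 2 alone 126. Genes with a CpG-rich promoter were marked in 9926 of 10061 cases (98.7%), and the remaining genes in 4818 of 11850 cases (40.7%). The domains had a median width of 2226 bp, and 5% of marked genes had one of 4893 bp or more. Across 14680 genes with a domain in every list, widths in the replicates correlated with a Spearman rho of 0.935 and differed by a median of 153 bp. Genes are not independent replicates, and neighbouring genes can share a domain.

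In the replicated list, all 38 limb patterning transcription factors and all 32 limb signalling genes carried H3K4me3, against 67.2% of other protein-coding genes (Fisher's exact test, adjusted p = 1.79e-06 and 1.12e-05). They included Tbx5, required for forelimb outgrowth, Tbx4 and Pitx1, which act in the hindlimb, and Prrx1, a marker of limb mesenchyme. Shh, the signal of the zone of polarizing activity, and Fgf8, a signal of the apical ectodermal ridge, were also marked, Shh at an enrichment of 7.05 and Fgf8 at 26.6. The mark also lies at poised promoters, so it does not show that either gene was active at this stage. In a stricter list, which keeps only replicated peaks at or above the median enrichment, the odds ratio fell from 37.5 to 5.29 for the transcription factors and from 31.7 to 3.47 for the signalling genes (adjusted p = 1.12e-04 and 0.00514, Fisher's exact tests). With the gene's 5' end only, these were 21.1 and 4.00 (adjusted p = 4.43e-06 and 0.00950, Fisher's exact tests). Of the cartilage genes, 22 of 24 were marked (adjusted p = 0.0143, Fisher's exact test). Sox9, Col2a1 and Acan were marked, while Col10a1, the collagen of hypertrophic cartilage, and Ucma were not. The cartilage call was lost without receptor genes in the background (adjusted p = 0.0609, Fisher's exact test), but held over CpG strata (adjusted p = 2.72e-04, Mantel-Haenszel test). In the stricter list the odds ratio turned from 5.35 to 0.799 (adjusted p = 0.707, Fisher's exact test). Among the osteoblast genes 9 of 16 were marked (adjusted p = 0.473, Fisher's exact test). The marked ones included Runx2 and Sp7, regulators of bone formation, and Col1a1, whereas the bone matrix genes Bglap, Dmp1 and Ibsp were unmarked. Joint and tendon genes were marked in 15 of 18 cases, including Scx and Gdf5 but not Kera, Prg4 or Tnmd (adjusted p = 0.242, Fisher's exact test).

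Lists for other cell types were compared with other genes in the same way. Of the endothelium genes 15 of 16 were marked (adjusted p = 0.0430, Fisher's exact test), with Tie1 as the exception. Emcn, counted as marked, had no peak in replicate 2. The endothelium call was lost without replicate 1 (adjusted p = 0.146), with 0.5 kb windows (0.354), with the gene's 5' end only (0.269) and without receptor genes in the background (0.0826, all by Fisher's exact test). It held in the pooled list (adjusted p = 0.00933, Fisher's exact test) and over CpG strata (0.00196, Mantel-Haenszel test). Skeletal muscle genes were marked in 25 of 30 cases, including Pax7, Myod1 and Myog, and epidermis genes in 18 of 22, including Krt5, Krt14 and Trp63. Neither list passed the test (adjusted p = 0.103 and 0.213, Fisher's exact test), although both did in the Mantel-Haenszel test over CpG strata (adjusted p = 6.46e-04 and 0.00898). In the pooled list both passed as well (0.0139 and 0.0277), and muscle genes did with 2.5 kb windows (0.0419, Fisher's exact tests). In the stricter list the endothelium, muscle and epidermis genes were marked less often than other genes, with odds ratios of 0.184, 0.160 and 0.299 (adjusted p = 0.00545, 4.52e-05 and 0.0111, Fisher's exact tests). Schwann cell and neural crest genes were marked in 11 of 16 cases (adjusted p = 1, Fisher's exact test), Sox10 and Egr2 among them. Blood lists were marked less often than other genes. Erythroid genes had the mark in 5 of 15 cases (adjusted p = 0.0160, Fisher's exact test), with Gata1 and Alas2 unmarked. Macrophage and leukocyte genes had it in 3 of 16 (adjusted p = 1.92e-04, Fisher's exact test), but in replicate 2 in 7 of 16, where the adjusted p was 0.0844, and in the pooled list it was 0.0702. The Mantel-Haenszel odds ratios over CpG strata were 0.444 (95% interval 0.123 to 1.60) for erythroid and 0.336 (0.0958 to 1.18) for macrophage and leukocyte genes, and neither list passed in that split.

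**Figure D2:**
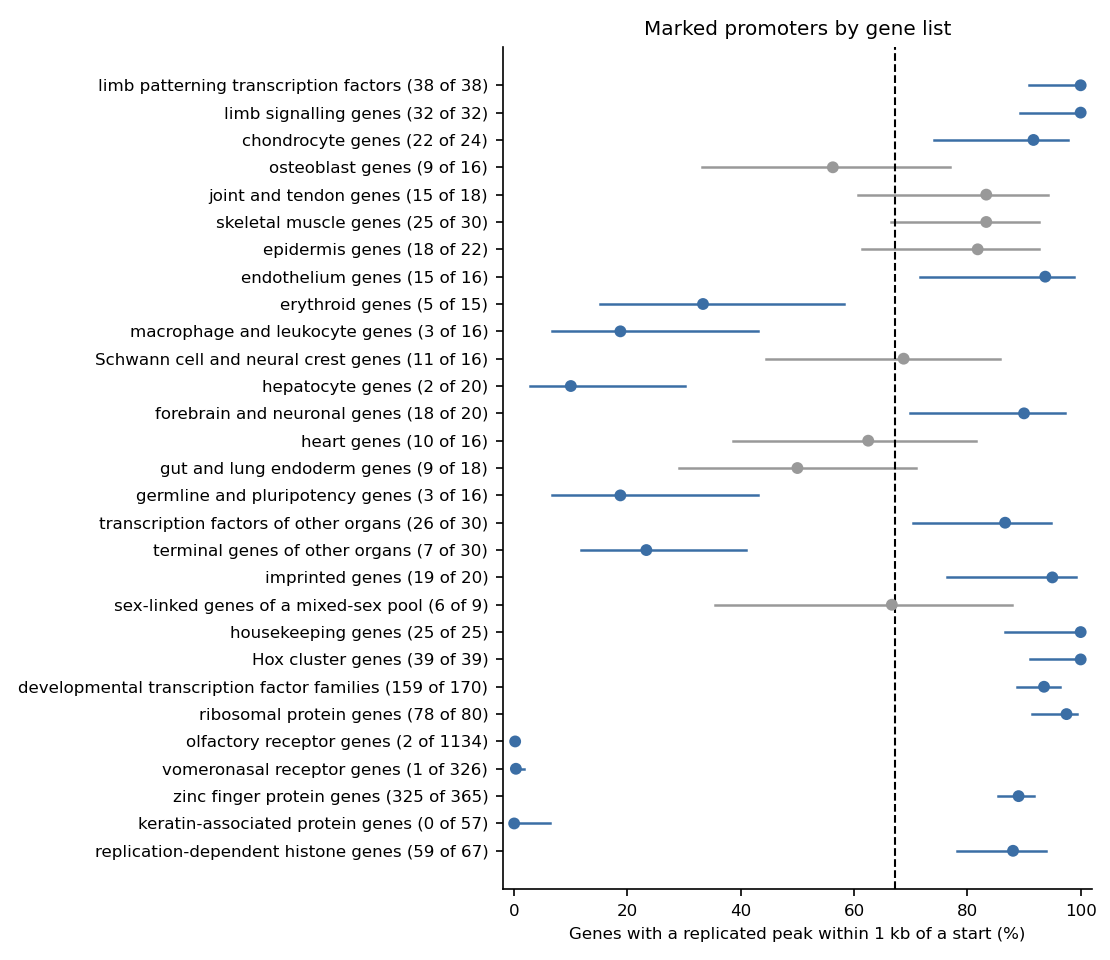
Percent of genes marked at a promoter (horizontal axis) for each gene list and family, with the number marked and the list size beside its name. Points are shares and lines 95% Wilson intervals, the dashed line is the 67.3% of all protein-coding genes, and blue stands for an adjusted p below 0.05; limb patterning and signalling lists lie at 100%.

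Genes of the 8 limb lists were marked in 174 of 196 cases (88.8%) and genes of the 5 other-organ lists in 42 of 90 (46.7%), an odds ratio of 9.04 (two-sided Fisher's exact test, p = 1.17e-13). The limb lists include the patterning and signalling regulators, all of them marked. Transcription factors of other organs, a separate list that shares members with the other-organ lists, were marked in 26 of 30 cases (86.7%). Tissue and gene class therefore cannot be told apart in this contrast. Hepatocyte genes were marked in 2 of 20 cases (adjusted p = 6.80e-07) and germline and pluripotency genes in 3 of 16 (adjusted p = 1.92e-04, both by Fisher's exact test). Alb, encoding serum albumin, and the pluripotency factor Pou5f1 were unmarked. The 2 marked hepatocyte genes were Apoh and Apoa1, and the Apoh domain also covers a start of Prkca. Heart genes (10 of 16, adjusted p = 0.849) and gut and lung endoderm genes (9 of 18, adjusted p = 0.169) did not pass the Fisher's exact test, although both passed as marked less often in the stricter list (0.00102 and 0.00188). Forebrain and neuronal genes went the other way and were marked in 18 of 20 cases (adjusted p = 0.0430, Fisher's exact test). This call was lost with 0.5 kb windows (adjusted p = 0.136), with 2.5 kb windows (0.0673), with the gene's 5' end only (0.722) and without receptor genes in the background (0.115, all by Fisher's exact test). It held in the pooled list (adjusted p = 0.0123, Fisher's exact test) and over CpG strata (0.00604, Mantel-Haenszel test). In the stricter list the neuronal genes were marked less often than other genes, with an odds ratio of 0.141 (adjusted p = 6.99e-04, Fisher's exact test). The difference between the limb and other-organ lists held among 76 and 23 genes with a CpG-rich promoter (100% against 78.3%, p = 4.70e-04) and among 120 and 67 remaining genes (81.7% against 35.8%, p = 4.40e-10, both by Fisher's exact test). The CpG-rich other-organ genes without the mark were Ddx4, Mael, Sycp1 and Sycp3 of the germline list and Slc17a6 of the neuronal list. The CpG-rich difference therefore rests mainly on germline genes.

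Transcription factors that specify other organs were marked in 26 of 30 cases, against 7 of 30 terminal genes of other organs, an odds ratio of 21.4 (two-sided Fisher's exact test, p = 1.32e-06). The marked factors included Foxg1 of the forebrain, Nkx2-1 of lung and thyroid and Nkx2-5 of the heart; Hnf1a, Hnf4a, Pdx1 and Phox2b were unmarked. With only the replicated peaks at or above the median enrichment, 1 of 30 factors and 3 of 30 terminal genes were marked, and the direction turned to an odds ratio of 0.310 (p = 0.612, Fisher's exact test). Of the marked terminal genes, Sftpc shares its domain with Bmp1. Against all other genes the factors had an adjusted p of 0.0430 and the terminal genes 2.89e-06 by Fisher's exact test, and in the Mantel-Haenszel test over CpG strata these were 0.0795 and 0.0702. The factors also did not pass with 0.5 kb windows (adjusted p = 0.0832), the gene's 5' end only (0.415) or a background without receptor genes (0.133), and in the stricter list they were marked less often (odds ratio 0.0275, adjusted p = 4.90e-09, Fisher's exact tests).

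Reference groups lay at both ends of the range. By Fisher's exact test, housekeeping genes (25 of 25, adjusted p = 1.47e-04), ribosomal protein genes (78 of 80, 1.06e-10), Hox genes (39 of 39, 1.12e-06), developmental transcription factor families (159 of 170, 9.18e-16) and imprinted genes (19 of 20, 0.0126) were marked more often than other genes. By the same exact test so were zinc finger protein genes (325 of 365, 1.58e-21) and histone genes (59 of 67, 2.40e-04), but within CpG strata the histone genes were marked less often, with an odds ratio of 0.200. Ribosomal protein genes had an odds ratio of 3.68 in that split (95% interval 0.867 to 15.6). In the stricter list the Hox, developmental transcription factor and histone genes were marked less often than other genes, with odds ratios of 0.355, 0.585 and 0.210 (adjusted p = 0.00291, 0.00105 and 3.42e-08, Fisher's exact tests). With the gene's 5' end only, the Hox odds ratio fell from 38.5 to 6.86 (adjusted p = 1.65e-04) and imprinted genes did not pass (adjusted p = 0.0979, Fisher's exact tests). Olfactory receptor genes were marked in 2 of 1134 cases, vomeronasal receptor genes in 1 of 326 and keratin-associated protein genes in 0 of 57, and each family passed the Fisher's exact test. Sex-linked genes were marked in 6 of 9 cases (adjusted p = 1, Fisher's exact test), with Xist and the Y-linked Ddx3y both marked in these pools of both sexes. Sry was unmarked. In the stricter list the sex-linked genes passed as marked less often (adjusted p = 0.00109, Fisher's exact test).

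Domain width set the limb regulators apart further. Marked limb patterning transcription factors had a median domain of 8383.5 bp against 2224 bp in other marked genes, and 34 of 38 lay in the widest 5% (permutation test, adjusted p = 6.57e-05). Several of them are Hox genes that share a domain. With each domain counted once, their 32 domains had a median of 7240 bp against 2154 bp (permutation test, adjusted p = 7.67e-05). Limb signalling genes had a median of 4397.5 bp, chondrocyte genes 4265 bp, imprinted genes 3959 bp and Hox genes 3614 bp. Each had the same adjusted p as the patterning genes taken per gene, 6.57e-05 by the permutation test. That value rests on the smallest p the permutations can give. Joint and tendon genes had a median of 3976 bp (adjusted p = 1.53e-04) and osteoblast genes 4071 bp (adjusted p = 0.00222, permutation test). Epidermis genes had a median of 3079 bp (adjusted p = 0.0135, permutation test). Without replicate 1, the adjusted p was 0.0614 for osteoblast and 0.0516 for epidermis genes. The osteoblast call was also lost with the gene's 5' end only (0.556), the epidermis call in the stricter list (0.722) and with merging within 0 bp (0.245), and the Hox call with merging within 0 bp (0.0873, permutation tests). Skeletal muscle (1973 bp), endothelium (2195 bp), erythroid (1855 bp), Schwann cell and neural crest (2347 bp), neuronal (2203 bp) and endoderm genes (3030 bp) did not pass the permutation test, with adjusted p-values from 0.117 to 0.941. Neither did the transcription factors (2352 bp) and terminal genes (1939 bp) of other organs, sex-linked genes (1538 bp) or housekeeping genes (2636 bp). Hepatocyte, macrophage and germline genes had fewer than 5 marked members and were not tested. Muscle genes passed as narrower with merging within 0 bp (adjusted p = 3.45e-04) and as wider in the stricter list (0.0435), and other-organ transcription factors as narrower with merging within 0 bp (0.0189, permutation tests). Merging within 3 kb made these factors (0.00159), endoderm genes (0.0396) and housekeeping genes (0.00184) pass as wider. Heart genes were narrower at 1513.5 bp (adjusted p = 0.0384, permutation test), but not without replicate 2 (adjusted p = 0.122), with 2.5 kb windows (0.123), with the gene's 5' end only (0.543) or with each domain counted once (0.0628), and merging within 3 kb turned the difference to 1699.5 bp wider (0.0123).

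Among the families, developmental transcription factors had a median of 3240 bp (adjusted p = 6.57e-05), histone genes 2971 bp (1.53e-04) and ribosomal protein genes 2762 bp (4.60e-04, permutation tests). Zinc finger protein genes had narrower domains, at 1895 bp (adjusted p = 6.57e-05, permutation test). Where each domain was counted once, the histone genes no longer passed (adjusted p = 0.0983, permutation test), nor did they in the stricter list (0.129) or with merging within 0 bp (0.568).

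**Figure D3:**
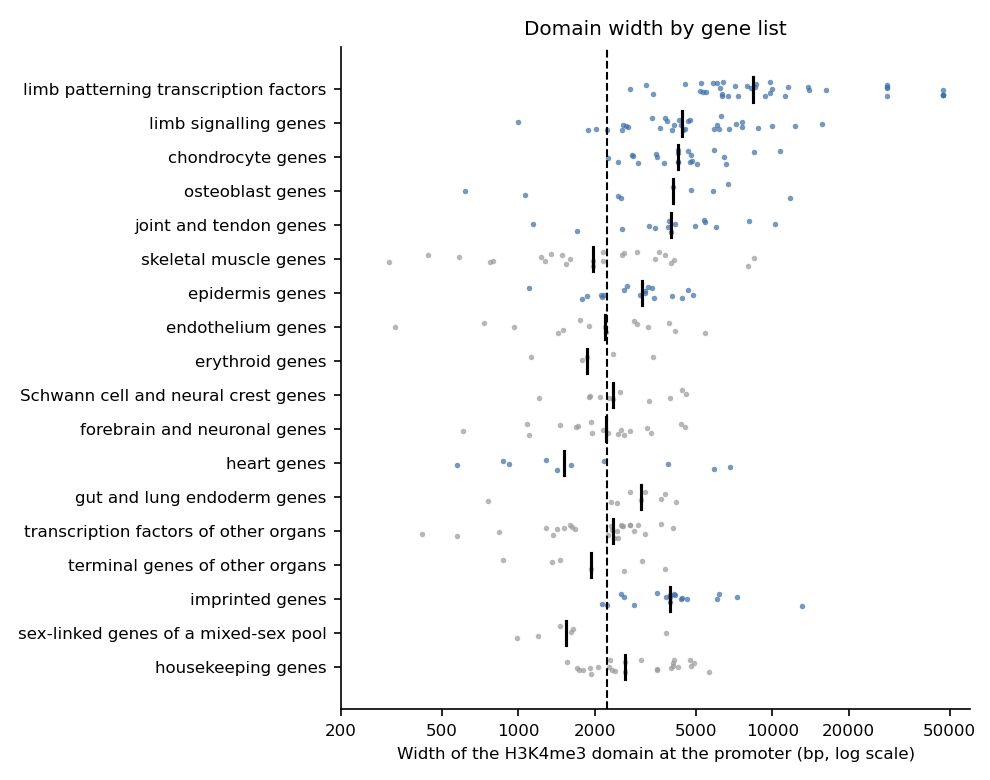
Width of the H3K4me3 domain at the promoter in bp on a log scale (horizontal axis) for each marked member of the fixed gene lists. Points are genes, short bars list medians, the dashed line is the 2226 bp median of all marked protein-coding genes, and blue stands for an adjusted p below 0.05; the limb patterning list has its median at 8383.5 bp.

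The widest domain covered the 5' part of the HoxA cluster, which patterns the limb along its length. It spanned chromosome 6, 52220135 to 52266952 (mm10), was 46818 bp wide and held starts of Hoxa7, Hoxa9, Hoxa10, Hoxa11 and Hoxa13. Its replicate widths averaged 46824.5 bp ± 793 (SD, n = 2). The second widest at promoters of protein-coding genes lay in the HoxD cluster on chromosome 2, 74666108 to 74694483, over the starts of Hoxd10 to Hoxd13, at 28376 bp (28752 ± 624, SD, n = 2). Both domains were assembled from several peaks lying within 1 kb of each other.

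**Figure D4:**
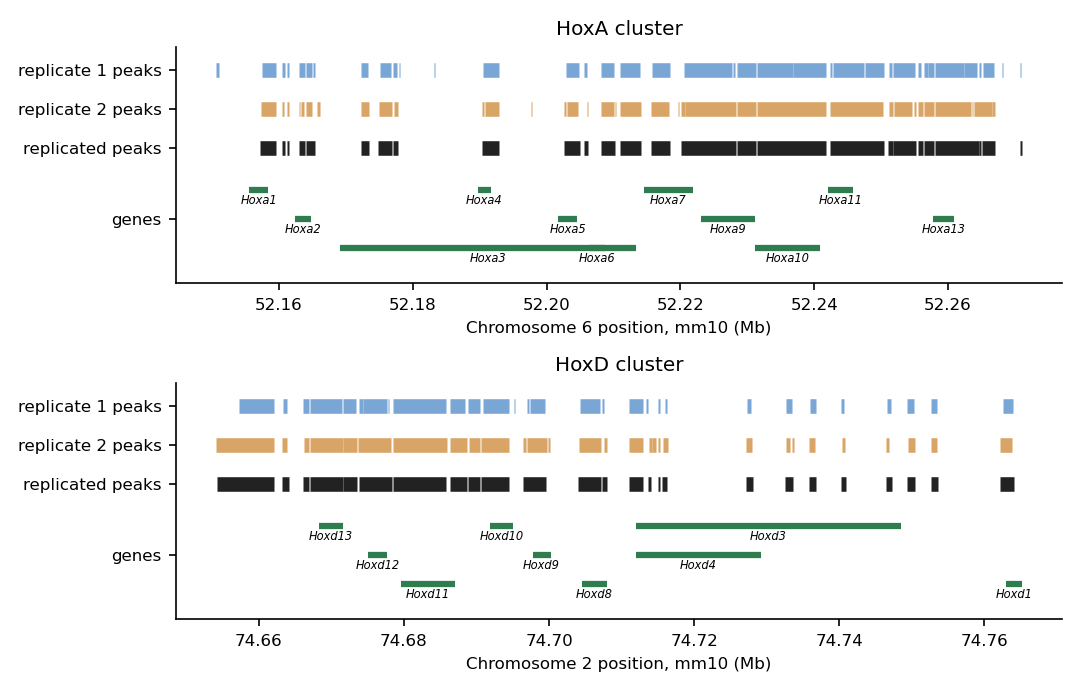
Map of the HoxA cluster on chromosome 6 and the HoxD cluster on chromosome 2, with mm10 position in Mb on the horizontal axis and rows for the peaks of replicate 1, replicate 2 and the replicated list and for the gene models. Bars are peaks or genes drawn to scale; near-continuous peaks run from Hoxa9 to Hoxa13, in a domain of 46818 bp, and from Hoxd10 to Hoxd13, in one of 28376 bp.

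The remaining 8 of the 10 widest domains at promoters of protein-coding genes were at Ebf3 (17542 bp), Tbx2 (16201 bp), Ptch1 (15672 bp), Nfib (14882 bp), Zfp503 (14483 bp), Gm42742 (14469 bp), Setd1b (14161 bp) and Tfap2a (14158 bp). Ptch1 encodes the hedgehog receptor, and its domain lay on chromosome 13, 63558388 to 63574059. The domain named for Gm42742 also covered starts of Kif22, Maz, Mvp, Pagr1a, Pagr1b and Prrt2. The Nfib domain was 14882 bp in the replicated list but averaged 10468.5 bp ± 92.6 (SD, n = 2) in the replicates alone.

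Among single genes of the limb, the Tbx5 domain was 13889 bp wide (replicates 14671 bp ± 1355, SD, n = 2; chromosome 5, 119829836 to 119843724), and that of Tbx4 was 6422 bp (6444 ± 218; chromosome 11, 85885756 to 85892177). Pitx1 had 7140 bp (6914 ± 124) and Prrx1 9340 bp (9280 ± 32.5). The spread between replicates was smaller than the difference between Tbx5 and Tbx4, which was not tested. In cartilage and bone, Sox9 had 6546 bp (7301.5 ± 589), Col2a1 6477 bp (6403.5 ± 44.5), Runx2 5860 bp (5608 ± 389) and Col1a1 11733 bp (11873 ± 243). In tendon and joint, Scx had 5391 bp (5152 ± 50.9) and Gdf5 4151 bp (4213.5 ± 88.4). Myod1 had 2610 bp (2686 ± 290), Krt5 2613 bp (2467.5 ± 23.3), and Nkx2-5 only 575 bp (765 ± 740).

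Away from promoters, 7222 replicated peaks lay on the chromosomes, and 17.3% of them overlapped an exon. The 5 strongest had widths of 1598 to 5277 bp. On chromosome 8, 69715117 to 69717671, an intergenic peak (enrichment 73.1) lay within 1 kb of a RefSeq start of Zfp869, and on chromosome 9, 67631743 to 67634714, another (69.7) lay within 1 kb of one of Tln2. A peak on chromosome 10, 13007801 to 13009861, was exonic in Sf3b5 (69.2) and lay within 1 kb of a RefSeq start of that gene. On chromosome 12, 8640198 to 8641795, an intergenic peak (67.0) lay 32339 bp from the nearest start, that of Pum2. The fifth, on chromosome 15, 85669681 to 85674957, was intronic in the noncoding gene Lncppara (66.5). The last 2 had no RefSeq start within 1 kb.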

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

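Neither group of peaks in this part entered the comparisons of gene lists in the replicated list. Both were counted in the shares of peaks by location or by retention, and neither was tested on its own. The replicated list held 11 peaks on 6 unplaced scaffolds, which carry no promoter in the annotation used. Their median enrichment was 10.02 and the highest was 52.2.

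A further 6487 pooled peaks were left out of the replicated list by the authors. Their median width was 236 bp and their median enrichment 2.54. Of these, 1822 (28.1%) lay at a promoter, 3199 (49.3%) in gene bodies and 1466 (22.6%) between genes, and 2064 overlapped no peak of either replicate.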

How the results depend on the processing

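The threshold of 2 on -log10 q, counting each domain once, leaving out shared windows and the CpG covariate were chosen after the data were seen. The limb against other-organ odds ratio lay between 7.42 and 12.03 under all 11 alternatives, each past the threshold. None of these alternatives separates tissue from gene class, and none leaves out a list. The range therefore does not show how far the contrast rests on single lists. Marked shares ran from 10% (hepatocyte) to 90% (neuronal) among the other-organ lists. Among the limb lists they ran from 56.25% (osteoblast) to 100% (patterning and signalling). No paired analysis was possible because there is 1 group. The split by CpG ratio gave no finite odds ratio for the limb patterning, limb signalling, housekeeping and Hox lists, where every gene was marked. Over single lists, 242 of the alternative shares and 240 of the widths kept direction and side of the threshold, 20 and 13 fell below it and 8 and 5 rose past it. Sex-linked genes passed as narrower without replicate 2 (-896 bp, adjusted p = 0.0344, permutation test). Why calls changed between settings was not tested. Depth limits calls at weakly marked promoters by an amount that these lists do not show.

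The stricter list of peaks at or above the median enrichment removes weak peaks by construction. It gave odds ratios of 0.310 for transcription factors against terminal genes, 0.799 for chondrocyte, 0.639 for joint and tendon, 0.160 for muscle, 0.299 for epidermis, 0.184 for endothelium, 0.799 for Schwann cell, 0.141 for neuronal, 0.0275 for other-organ transcription factor, 0.355 for Hox, 0.585 for developmental transcription factor and 0.210 for histone genes. There 6 lists were marked more often and 19 less often. The muscle odds ratio was 0.985 with the gene's 5' end only, and the Schwann cell one 0.852 without receptor genes. The CpG split turned osteoblast (1.27), heart (1.48) and histone genes (0.200).

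Width differences turned for endothelium (52.5 bp pooled, 144.5 bp without replicate 1, 39 bp with each domain counted once), neuronal (58.5 bp without replicate 1, 47 bp per domain) and muscle genes (69 bp without replicate 2, 1283 bp in the stricter list). Leaving out either replicate gave -38.5 to 144.5 bp for endothelium, -274.5 to 58.5 bp for neuronal and -331 to 69 bp for muscle genes. They also turned for other-organ transcription factors (-480.5 bp, merging within 0 bp) and heart genes (1699.5 bp, within 3 kb). Narrower lists numbered 1 with 2.5 kb windows, the stricter list, the 5' end, 3 kb merging or single domains, and 4 with 0 bp merging, against 2.

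Peaks at starts made up 67.4% (0.5 kb), 76.3% (2.5 kb), 61.1% (pooled), 96.1% (stricter list) and 59.9% (5' end), and 63.0 to 64.1% without either replicate. Replicate overlap was 75.9 and 75.2% (reciprocal), 98.8 and 97.5% (stricter lists) and 91.0 and 87.2% (-log10 q of at least 2). Shares kept in the replicated list were 77.4 and 78.5% (reciprocal) and 83.8 and 82.7% (stricter lists). For the stricter shares each list was cut at its own median enrichment, which was higher in the replicated list than in either replicate. In the whole replicated list, 100% of the peaks in both upper quartiles of either replicate were kept. The stricter shares therefore do not show that strong peaks were kept less often. Promoters of replicate 1 alone numbered 55 in the stricter lists.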

Other observations

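The enrichment of the lists, the width comparison between patterning genes, the values by Hox cluster, the shifts, strong subset and weakest peaks set beside the peaks away from promoters, the shares of peaks that did not overlap and the CpG covariate were chosen after the data were seen; the other tests were set before. Marked limb patterning transcription factors had wider domains than marked transcription factors of other organs, with medians of 8383.5 and 2352 bp (permutation test, adjusted p = 1.30e-04). This test was made per gene, so shared Hox domains entered it more than once. With each domain counted once, the patterning median was 7240 bp. The enrichment values that follow describe the peaks on the caller's scale. The 38 limb patterning transcription factors had a median enrichment of 40.9 (quartiles 30.5 and 49.7), and the 26 marked transcription factors of other organs 13.03 (6.83 and 16.2). Skeletal muscle genes had a median of 5.89 and endothelium genes 9.71, with 16 of 25 and 8 of 15 below 10, against 54.1 in other marked genes. Chondrocyte genes had 28.5 and housekeeping genes 62.8.

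The Hox clusters were marked throughout but unequally. In HoxA, paralogues 9 to 13 lay in 1 domain with a median enrichment of 49.5, and in HoxD in 2 domains with a median of 26.0. In HoxB and HoxC the same paralogues had medians of 10.5 and 13.6 and widths of at most 2194 and 5311 bp. Paralogues 1 to 8 had medians of 34.9 in HoxA, 10.5 in HoxB, 14.7 in HoxC and 22.5 in HoxD. Neighbouring Hox genes share domains, so these values were not tested.

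The gene groups that differed in marking also differed in promoter CpG content, a candidate explanation for both contrasts. The median CpG ratio was 0.619 in transcription factors and 0.240 in terminal genes of other organs. Stratifying by CpG ratio left an odds ratio of 8.63 (95% interval 1.96 to 37.9) for that contrast and 9.34 (4.82 to 18.1) for limb against other-organ lists. With the ratio as a covariate they were 5.36 (1.08 to 26.7) and 12.03 (5.68 to 25.5). Both contrasts thus remained beside the CpG ratio at the gene's 5' end. A gene counted as marked at any of its starts, so the ratio can describe another start than the marked one. Runx2, for example, had a ratio of 0.164 at its 5' end and its domain inside the gene. How far CpG content accounts for either contrast therefore cannot be told here. Only 1 terminal gene was CpG-rich, so the stratified value of the first contrast rests on 9 of 13 against 6 of 29 remaining genes. No biological explanation was tested.

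Peaks away from annotated starts may mark promoters missing from the annotation used. Of these 7222 peaks, 882 (12.2%) lay within 1 kb of a RefSeq start, against at most 2.29% after circular shifts. This argues against RefSeq-listed starts as the source of most of them, though among the 463 at or above the list's median enrichment the share was 34.8%. Starts absent from both annotations stay open. A -log10 q below 2 was found in 0.582%, a share that could not exceed 0.886% in the replicated list, so it decides nothing. Even the weakest 7222 replicated peaks had a median of 8.79. The peaks away from starts had a median of 14.9 and a lower quartile of 6.84. The pooled peaks left out had a median of 2.40 and a 95th percentile of 5.58, and the lowest pooled value was 0.234. Most of the peaks away from starts thus lay above 5.58. Any 7222 replicated peaks would have had a median above that value, so the comparison could not have come out otherwise. Whether weak calls near the threshold account for these peaks therefore cannot be told from it. The values of the left-out peaks were added after the data were seen. No biological explanation was tested.

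For promoters called in 1 replicate only, weak calls near the threshold cannot be told apart from other sources. Of the 253 peaks behind them, 193 (76.3%) lay in the lowest enrichment quartile of their list, but so did 90.7% of all replicate 1 peaks and 87.0% of all replicate 2 peaks that the other replicate did not overlap, so a low share was hardly possible. Their median widths were 244 bp in replicate 1 and 247 bp in replicate 2. A difference between the embryo pools stays open and was not tested.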
